A study of Homo sapiens with 4 samples.

How the data were processed

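Ribosome profiling was carried out in 4 samples of 2 established human cell lines, 2 samples of K562 and 2 of HepG2. In this assay, fragments of messenger RNA that ribosomes protect from digestion (footprints) are isolated and sequenced. Per the labels' protocols, cells were lysed in a buffer with cycloheximide, which arrests elongating ribosomes, footprint-sized RNA was isolated, and ribosomal RNA was removed with RiboZero. cutadapt, Bowtie2 and STAR 2.6.0 are named in the submitters' processing notes, with the human build GRCh38 and without the role of each tool. The annotation release and the program that counted the junctions are not given in the sources used here.

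The deposited files used here hold 1 table per cell line, and both samples of a line share it, per the labels. The deposited values are raw read counts per annotated splice junction, in a column of all mapped reads and a column of uniquely mapped reads, per the file headers. Each table lists the same 350863 junctions with position, strand, transcript and gene identifier. No column separates the samples of a line, so neither a standard deviation nor a test across samples was computed. Signal tracks of the series are not analysed here, and each count refers only to footprints that span a junction.

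Each junction was matched to the introns of the GENCODE annotation, release 29, on GRCh38. An exact match was found for 350016 junctions (99.8%), and 34914 of the 35316 gene identifiers had an annotation record. Symbols came from a name table that held 34661 of the identifiers. Junctions were classed as joining coding parts, as lying in a 5′ or 3′ untranslated region, or as noncoding, and coding was given precedence where transcripts disagreed.

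Uniquely mapped reads were summed per gene over junctions of 1 gene, which left out the 6033 junctions assigned to more than 1 gene. Genes with 20 or more reads over both tables were kept. TMM factors from edgeR 4.0.16 set the effective depth of each table. The ratio of K562 to HepG2 was given an exact 95% conditional binomial interval (Clopper-Pearson), which covers counting error only, since reads without molecular identifiers are not independent molecules. A gene was counted as higher in a line when the whole interval lay past 2-fold. An observed count of 0 was set to a floor of 3 counts per table, so that such ratios depend on the floor and enter list medians at that value. For single genes with a count of 0, a fold given with "at least" is the bound of the exact interval. With all mapped reads, a multi-mapped read may be counted at more than 1 place, so intervals from that column are too narrow and it served only for alternatives and for reads outside the comparisons. These calls compare the tables as deposited and carry no information on the variation between cultures.

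The 21 gene lists, the size rules, the alternatives and the rule for named genes were fixed before the data were examined. For each list, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean count in 20 bins. The share of a junction among all junctions with the same donor or acceptor was compared at sites with 20 or more reads in each line. A junction was counted when the shares differed by at least 20 percentage points and their exact 95% intervals did not overlap. Named genes were, by rule, MTAP, CDKN2A and CDKN2B as a check of the labels, and the 12 genes at each end of the ranking by interval bound. The rule added up to 4 members per list with the most reads, up to 2 members past 2-fold against the list median, the 10 genes with the largest junction share differences, every counted junction of a splicing list, and the 6 most-read long noncoding genes. Any other gene named is a list member or was chosen after its values were seen. Some genes that these rules name, and 1 of the gene lists, are not reported here.

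Simulated counts were tested first, and those of genes had the depth of the real tables. In the comparison of genes, run on 10845 simulated genes, 4 of 50 genes with a true 2-fold difference were counted, as were 42 of 50 at 3-fold, 47 of 50 at 4-fold and 50 of 50 at 8-fold. Of the genes simulated at 2-fold, 1 fell below the read minimum, so it is not among the 10845 and stands among those not counted. None (0) of 10646 unchanged genes was counted, and 96.07% of intervals held the true ratio. In the comparison of junction shares, run on 2000 simulated sites, 196 of 200 sites changed by 40 points and 3 of 1800 unchanged sites were counted. The simulations contained counting error only. Few simulated genes were changed, equally up and down, so the simulations do not show how the choice of scaling affects calls in the real tables.

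The alternatives were scaling by total reads, DESeq2 1.42.0 size factors, all mapped reads, minimums of 100 and of 1 read per gene, 99% intervals, junctions of more than 1 gene counted for each gene, the most-read junction of each gene left out, coding junctions only, and thinning to the smaller total. Stricter read and share limits were applied to junction usage, and other region definitions to region shares. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.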

Results

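Footprints that span splice junctions were compared between K562, an erythroid-like line from a chronic myelogenous leukemia, and HepG2, a hepatocyte-like line from a liver tumor. The labels give 2 samples of each line, and the junction counts are pooled to 1 table per line. The K562 table held 10118105 mapped junction reads, of which 7487508 (74.0%) were uniquely mapped. The HepG2 table held 12001095, of which 9927809 (82.7%) were uniquely mapped. The 10 genes with the most reads took 15.9% of single-gene reads in HepG2 and 4.21% in K562. There is no replicate check for any value here, and the intervals given are exact 95% intervals that cover counting error only.

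Genes at known features of these lines were read first, as a check of the labels. K562 is known to lack a part of chromosome 9p21 that holds CDKN2A, CDKN2B and MTAP. MTAP (ENSG00000099810, chromosome 9, 21802543 to 21937651), an enzyme of methionine salvage, had 0 reads in K562 and 249 in HepG2, at least 67.3-fold lower in K562. CDKN2A had 0 reads in K562 and 8 in HepG2, and CDKN2B had 0 and 1, both too few for the gene comparison.

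The first comparison asked which genes had more footprints in one line than in the other. The 12 genes at each end of the ranking are given here with their reads. RHAG (ENSG00000112077, chromosome 6, 49605158 to 49636884), an ammonium channel of the red cell membrane, had 7365 reads in K562 and 0 in HepG2, at least 1987-fold higher. LDHB (ENSG00000111716), a lactate dehydrogenase subunit, had 17589 reads in K562 and 4 in HepG2, a ratio of 4377 (1709 to 16066). VIM (ENSG00000026025), the intermediate filament vimentin, had 22706 and 9 reads, a ratio of 2511 (1323 to 5492). ANXA1, a phospholipid-binding annexin, had 13546 and 8 reads, and the neuropeptide gene NMU had 6809 and 2. MSN, which links actin to the membrane, had 6540 and 2 reads, ZNF595 had 8908 and 3, with a log2 ratio of 5.66 without its most-read junction, and GTSF1 had 8064 and 4. MS4A3, SAMSN1, ARHGDIB and CD81 had 6303, 5057, 3211 and 3148 reads in K562 and 0 in HepG2.

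At the other end, ALB (ENSG00000163631, chromosome 4, 73397114 to 73421412), which encodes albumin, had 349063 reads in HepG2 and 41 in K562, a ratio of HepG2 to K562 of 8553 (6305 to 11919). ITIH2, an inter-alpha-trypsin inhibitor heavy chain, reached a ratio of 15310 (6560 to 47152) from 76193 and 5 reads. The fibrinogen chain FGG had 71823 and 6 reads, the apolipoproteins APOB and APOH had 120618 and 17 and 42313 and 3, and the protease inhibitors SERPINA1 and A2M had 64084 and 7 and 141045 and 25. GPC3, a glypican of fetal liver and liver tumors, had 32423 reads in HepG2 and 1 in K562, a ratio of 32574 (5846 to 1286650). AHSG had 42114 and 3 reads, AMBP 40496 and 4, and the fatty acid binding protein FABP1 22004 and 1. AGT, the precursor of angiotensin, had 11732 and 0 reads and was at least 3195-fold higher in HepG2.

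Of 10956 genes, 1836 were higher in K562 and 2402 higher in HepG2 by the 2-fold rule, and 6718 were past neither limit. K562 thus took 43.3% of the calls. With scaling by total reads, the median log2 ratio of all genes shifted from -0.01 to 0.41, and 2656 and 1925 genes were counted, with 58.0% of the calls in K562. Directions below are therefore relative to the TMM scale. Of 1208 genes higher in K562 that had 3 or more junctions with 10 or more reads, 953 had every such junction on the K562 side, and the same held on the HepG2 side for 1589 of 1810 genes.

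Genes of liver function formed the groups with the lowest ratios. Of 26 genes for plasma proteins, 26 were higher in HepG2, with a median log2 ratio of K562 to HepG2 of -12.12. They took 15.1% of the HepG2 gene reads and 0.0307% of the K562 gene reads. AFP, the fetal counterpart of albumin, had 371360 reads in HepG2 and 162 in K562, and the iron carrier TF had 113638 and 25. Of 21 coagulation and complement genes, 20 were higher in HepG2 (median -6.19), among them C3 with 97115 and 112 reads, F2 (prothrombin) with 8013 and 1, C5 with 3624 and 3, and SERPINC1 (antithrombin) with 2960 and 0. All 8 measured hepatocyte transcription factors were higher in HepG2 (median -5.66), with HNF4A at 1545 and 0 reads, NR1H4 at 733 and 0, HNF4G at 268 and 0, and PROX1 at 180 and 0. Of 18 genes of hepatic metabolism and transport, 16 were higher in HepG2 (median -4.80). ALDH1A1, a retinal dehydrogenase, had 7385 and 299, and PCK2 had 1892 and 349, whereas FAH had 1278 and 1368 and a ratio of K562 to HepG2 of 1.07 (0.987 to 1.15). The medians of these 4 lists lay below those of all 10000 random lists.

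The sterol list, the epithelial list and the list of iron and acute phase genes had medians toward HepG2, with exceptions in each list. Of 20 sterol genes, 11 were higher in HepG2 and 8 passed neither limit (median log2 ratio -1.38). FDFT1 and FDPS, of the shared pathway to sterols, had ratios of HepG2 to K562 of 1.53 and 1.69 and did not pass 2-fold. INSIG1 was the exception with 82 reads in K562 and 0 in HepG2. Of 16 epithelial genes, 10 were higher in HepG2 and 6 passed neither limit (median -2.05), among them KRT19 and JUP, with ratios of K562 to HepG2 of 1.88 and 1.87. With total-read scaling, 2 epithelial genes were higher in K562. The desmosome gene DSP had 4091 reads in HepG2 and 0 in K562, LAMB1 had a ratio of 9.52 (8.73 to 10.4) and EPCAM of 4.16 (3.90 to 4.45). The keratin gene KRT18 had a ratio of 2.96 (2.77 to 3.17), but only 26.3% of its reads were uniquely mapped, and without its most-read junction the log2 ratio of K562 to HepG2 turned to 0.13. Of 13 iron and acute phase genes, 9 were higher in HepG2 (median -4.26), among them FGB with 23848 and 5 reads, CP (ceruloplasmin) with 2640 and 0, and ACO1 with a ratio of 2.78 (2.53 to 3.05). This list shares members, FGB among them, with the plasma protein list, so its median partly repeats that result. IREB2, with 1286 and 1279 reads, had a ratio of HepG2 to K562 of 1.01, and the iron exporter gene SLC40A1 was higher in K562, with 272 reads against 20.

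Red cell proteins, blood transcription factors and blood cell signalling were the lists with the highest medians, and heme synthesis differed less. Of 13 measured red cell genes, 10 were higher in K562 and 3 passed neither limit (median log2 ratio 7.69). The glycophorin GYPB had 1279 reads in K562 and 0 in HepG2, and EPB41, a protein of the red cell membrane skeleton, had a ratio of 4.54 (4.20 to 4.91). The transferrin receptor gene TFRC, with 10273 and 11898 reads, had a ratio of 0.859 (0.837 to 0.882). The globins HBA1, HBA2, HBZ, HBG1 and HBG2 had no uniquely mapped reads and are not among the 13 genes. Of 14 erythroid and blood transcription factors, 11 were higher in K562 (median 5.18). MYB had 3091 reads and 1, GATA1 776 and 0, LMO2 587 and 0, and LDB1 had a ratio of 3.22 (2.77 to 3.76). Of 20 genes of blood cell signalling, 17 were higher in K562 (median 5.72), among them the actin-bundling gene LCP1 with 11446 and 43 reads and PTPRC, the CD45 antigen, with 1988 and 2. INPP5D with 33 and 445 reads, CORO1A with 37 and 111 and PTPN6 with 12 and 134 were higher in HepG2. Of 9 genes of heme synthesis, 3 were higher in K562 and 5 passed neither limit (median 0.63, above 91.2% of random lists), among them UROD at 4.05 (3.81 to 4.31). ALAD was higher in HepG2, with a ratio of 2.95 (2.37 to 3.69), and CPOX and ALAS1 had ratios of K562 to HepG2 of 0.531 and 0.786.

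Ribosomal protein genes were shifted toward K562 by smaller amounts, and translation factors less clearly. Of 41 large-subunit ribosomal protein genes, 17 were higher in K562 and 0 in HepG2 (median log2 ratio 0.95). Of 29 small-subunit genes, 16 were higher in K562 and 1 in HepG2 (median 1.18). RPL37 had a ratio of 4.93 (4.78 to 5.08), RPL35A of 2.33 (2.29 to 2.38) and RPL11 of 2.30 (2.24 to 2.37), while RPL30 had 0.719 (0.707 to 0.732). RPS24 and RPS19 had ratios of 2.58 and 2.11, and RPS21 had 0.764. RPS7 was counted as higher in HepG2 from 21 and 106 unique reads, but its log2 ratio turned to 0.13 with all mapped reads. Only 38.0% of the reads of the large-subunit genes and 44.4% of those of the small-subunit genes were uniquely mapped, so values of single members are uncertain. With only junctions 60 or more coding bases after the start codon, an alternative chosen after seeing the data, the log2 ratios of RPS24 and RPS19 were 0.59 and 0.27, and those of RPL35A, RPL37 and RPL11 were 0.78, 1.97 and 1.06. The list medians were then 0.86 and 0.69, and 13 of 34 and 7 of 24 genes were higher in K562. The log2 ratio of RPL30 turned to 0.54 without its most-read junction. Of 25 translation factors, 4 were higher in K562 and 2 in HepG2 (median 0.53, above 96.2% of random lists). The elongation factor EEF2 had a ratio of 2.27 (2.22 to 2.32), EIF3D and EIF3B had 1.88 and 1.05, EIF5B lay between 1.44 and 1.56, and EIF6 and EIF2S2 were higher in HepG2, with ratios of HepG2 to K562 of 2.36 (2.22 to 2.52) and 5.84 (4.35 to 7.97). Only 4.2% of the EIF2S2 reads were uniquely mapped, and with all mapped reads its log2 ratio of K562 to HepG2 was -0.45, short of 2-fold.

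Genes of protein folding in the endoplasmic reticulum were shifted toward HepG2. Of 22 folding and unfolded protein response genes, 14 were higher in HepG2 (median log2 ratio -1.66). The ratio of HepG2 to K562 was 7.45 (7.20 to 7.71) for P4HB, a disulfide isomerase, 3.49 (3.41 to 3.58) for the chaperone gene CALR and 3.07 for HSP90B1, while CANX was at 1.26 (1.23 to 1.28). ASNS, which makes asparagine, and SDF2L1 were higher in K562, with ratios of 2.71 (2.53 to 2.90) and 5.09 (4.14 to 6.30). The ribosomal protein medians exceeded those of at least 99.99% of random lists. The folding median lay below those of all 10000 random lists.

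Genes of proliferation, energy metabolism and stroma went in both directions within each list. Of 24 genes of DNA replication and mitosis, 4 were higher in K562, 1 in HepG2 and 19 passed neither limit (median log2 ratio 0.13). TOP2A, MCM3 and CCNB1 had ratios of K562 to HepG2 of 1.09, 1.06 and 1.36, and the exception in HepG2 was PCNA, with a ratio of HepG2 to K562 of 2.70 (2.61 to 2.78). PCNA, like EIF6 and EIF2S2 above, lies on chromosome 20. The median ratio of HepG2 to K562 over 301 genes of that chromosome, relative to all genes, was 2.47. Of 22 genes of oxidative phosphorylation, 19 passed neither limit (median 0.12), and ATP5F1A, ATP5F1C, ATP5F1B and UQCRC2 had ratios of K562 to HepG2 of 0.961, 1.12, 1.20 and 0.578. SDHB and COX5A were higher in K562, at 2.50 (2.35 to 2.67) and 2.12 (2.03 to 2.22), and UQCRC1 was higher in HepG2, at 2.25 (2.14 to 2.37). Of 19 glycolytic genes, 4 were higher in each line, and the median of -0.67, above 2.22% of random lists, and the mean of 0.71 differ in sign. LDHB and the hexokinase HK1, with 2419 and 6 reads, were higher in K562, LDHA was higher in HepG2 at 2.41 (2.34 to 2.49), and ENO1, ALDOA and PGK1 had ratios of K562 to HepG2 of 1.02, 0.630 and 1.65. Of 7 fibroblast and stroma markers, 3 were higher in each line, and the median of -0.71 and the mean of 0.69 differ in sign. VIM and COL1A2, the latter with 210 and 0 reads, were higher in K562, ACTA2 with 5 and 1087 reads was higher in HepG2, and S100A4 was at 0.613. With a minimum of 100 reads, 4 of the 7 remained and their median was 2.72.

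**Figure D1:**
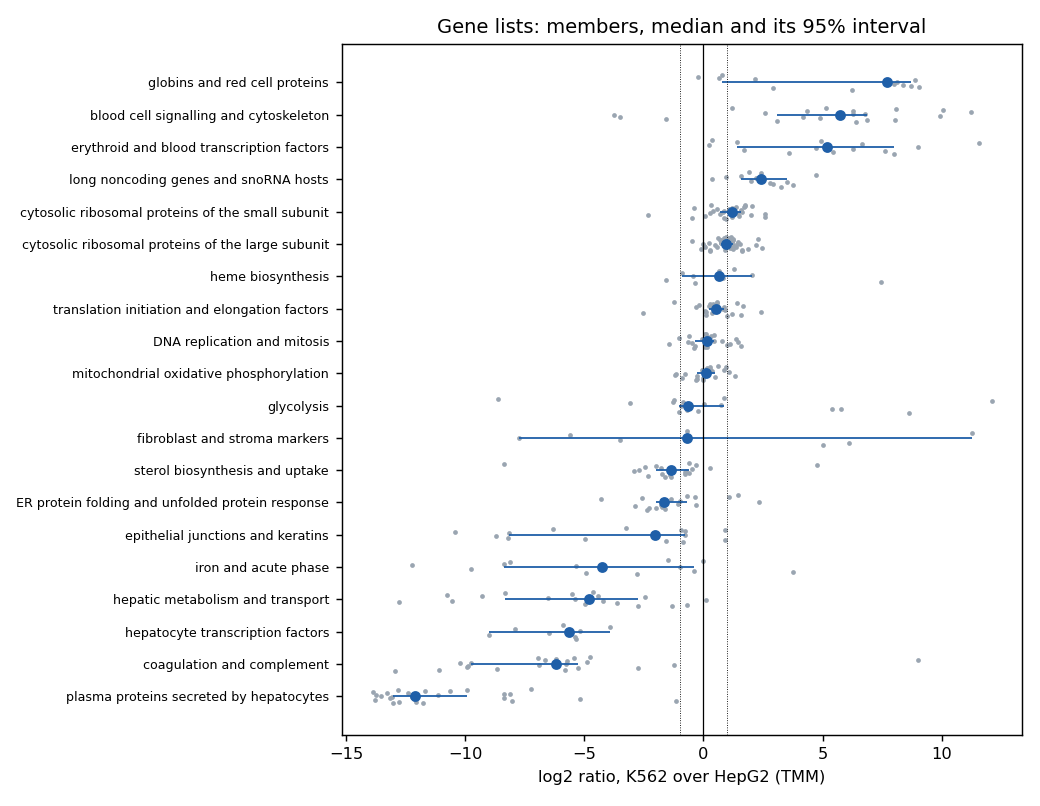
Small points are the log2 ratios of K562 to HepG2 of the measured members of 20 gene lists, large points are list medians, bars are exact 95% intervals of the median over members, and dotted lines mark 2-fold. Medians run from -12.12 for plasma proteins to 7.69 for red cell proteins.

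Long noncoding genes had more footprint-sized reads at junctions in K562. Of 267 such genes, 122 were higher in K562, 36 higher in HepG2 and 109 past neither limit, and they took 0.725% of the gene reads in K562 and 0.133% in HepG2. Of 13 long noncoding genes in the list of snoRNA hosts and related genes, 10 were higher in K562 and 0 in HepG2 (median log2 ratio 2.43). The snoRNA hosts SNHG29, SNHG8 and SNHG5 had ratios of 4.66 (4.45 to 4.88), 11.3 (10.4 to 12.3) and 7.50 (6.91 to 8.17). GAS5 and SNHG1 had ratios of 9.53 and 13.4, and ZFAS1, at 1.93 (1.81 to 2.06), did not pass the rule.

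The next comparison asked how junction reads were divided between parts of transcripts. Junctions that join coding parts took 92.1% (92.1 to 92.2) of unique reads in K562 and 96.2% (96.2 to 96.3) in HepG2. Junctions in 5′ untranslated regions took 6.54% (6.52 to 6.56) in K562 and 3.29% (3.27 to 3.30) in HepG2. Noncoding junctions took 1.19% (1.18 to 1.20) and 0.325% (0.322 to 0.329). Junctions in 3′ untranslated regions took 0.128% (0.125 to 0.130) and 0.149% (0.147 to 0.152), and this difference changed sign with all mapped reads. All these levels depend on the precedence given to coding. With untranslated annotation first, coding junctions took 31.3% in K562 and 37.8% in HepG2, and 5′ untranslated junctions 10.4% and 6.41%. In that order, 3′ untranslated junctions took 19.8% and 20.7%, and noncoding junctions 38.6% and 35.0%. Within 1423 genes with reads in both parts, the ratio of 5′ untranslated to coding reads was higher in K562 in 1141, by a median of 1.70-fold (log2 0.77, 0.70 to 0.81).

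Reads in 5′ untranslated regions were concentrated at junctions next to the start codon. Junctions up to 9 bases before it had 70.6 reads on average in K562 and 47.1 in HepG2, against 11.7 and 9.89 at 10 to 30 bases. At 31 to 100 bases the averages were 8.61 and 4.80, and beyond 100 bases 3.81 and 2.30. Among the most-read junctions in K562 were those of RPS19 and BTF3, both 0 bases from the start codon, with 19293 and 16615 reads in K562 and 5910 and 11803 in HepG2. In HepG2, the SERPINA1 junction at 4 bases had 30802 reads and the APOA2 junction at 24 bases 12909, and each had 3 in K562. These genes were chosen after their values were seen.

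**Figure D2:**
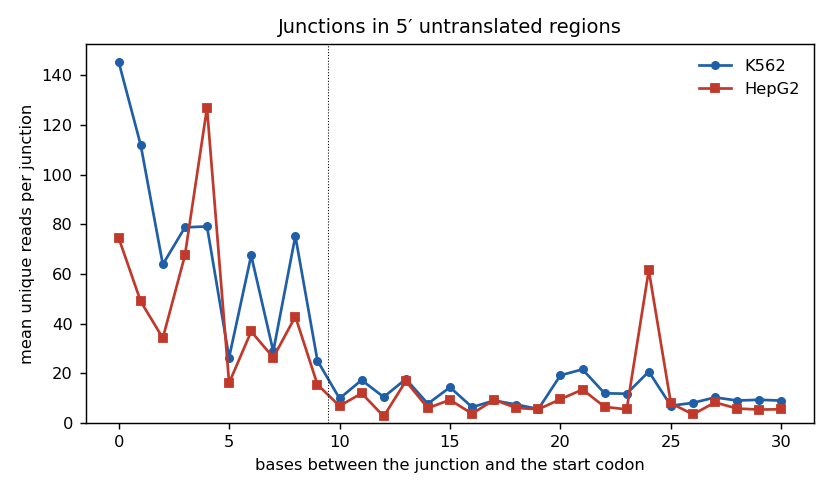
Mean number of unique reads per annotated junction in 5′ untranslated regions, by the number of bases between junction and start codon, for K562 (circles) and HepG2 (squares); the dotted line lies after 9 bases. The HepG2 points at 4 and 24 bases rise with single genes, SERPINA1 and APOA2.

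Detection was similar in number. At least 1 unique read was seen at 124243 junctions in K562 and 126575 in HepG2, and 101158 were seen in both. After thinning to the smaller total, HepG2 had 121647. Junctions with 5 or more reads numbered 81963 in K562 and 87568 in HepG2.

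The last comparison asked where the lines used different junctions of the same gene. Shares were measured at 17213 splice sites in 5184 genes, and 943 junctions in 451 genes passed the rule. Of these, 661 joined coding parts and 214 lay in 5′ untranslated regions. Since the shares at a site are complementary, 1 change can count more than 1 junction. A junction of GSKIP in the 5′ untranslated region (chromosome 14, 96379756 to 96382246) took 587 of 587 reads at its acceptor in K562 (99.4 to 100%) and 0 of 664 in HepG2 (0 to 0.554%). A junction of KCNAB2 (chromosome 1, 5992789 to 6040516) took 41 of 41 reads in K562 and 0 of 20 in HepG2. A coding junction of the ubiquitin ligase gene NEDD4L (chromosome 18, 58044709 to 58390645) took 0 of 38 reads in K562 and 285 of 324 (88.0%) in HepG2. ST7 had a junction with 178 of 230 reads in K562 and 0 of 28 in HepG2, and DMTN, a red cell membrane skeleton gene, one with 36 of 43 and 0 of 31. STXBP4 had one with 26 of 31 and 0 of 61. In RAD51AP1, SMYD3, SORT1 and DRAM2, the named junction was used more in HepG2, with shares of 92.9%, 100%, 100% and 100% against 4.76%, 13.4%, 22.2% and 24.4% in K562.

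**Figure D3:**
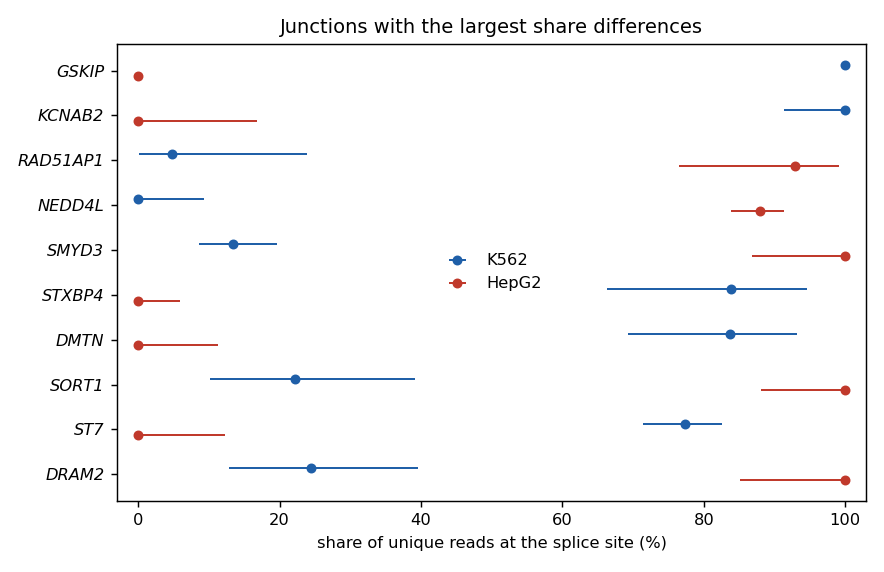
Share of the unique reads at a donor or acceptor that one junction took, for the 10 genes with the largest differences, in K562 (blue) and HepG2 (red), in percent with exact 95% binomial intervals. GSKIP goes from 100% in K562 to 0% in HepG2.

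Of 47 genes with well-known alternative exons, 35 were measured, and 8 had a counted junction. In APLP2, an exon of 168 bases (chromosome 11, 130123612 to 130123779) was entered by 374 reads and skipped by 52 in K562, an inclusion of 87.8% (84.3 to 90.7), and by 233 and 292 in HepG2, 44.4% (40.1 to 48.7). From the junction that leaves the exon, inclusion was 65.3% and 31.3%, so levels depend on the side counted. In EPB41, an exon of 63 bases (chromosome 1, 29060422 to 29060484) was included in 12.2% (9.17 to 15.7) in K562 and 61.5% (47.0 to 74.7) in HepG2 on the entering side, and in 23.8% and 69.7% on the leaving side. In PICALM, an exon of 24 bases (chromosome 11, 85978070 to 85978093) was included in 24.4% (12.4 to 40.3) and 78.6% (69.8 to 85.8) on the entering side, but in 0 of 31 and 11 of 35 reads on the leaving side. An exon of NUMB of 33 bases was included in 21.8% and 44.3% on the entering side and in 22.8% and 21.3% on the leaving side, so only 1 side differed. At counted acceptors, one CTTN junction took 45.5% of the reads in K562 and 21 of 100 in HepG2, one MBNL1 junction 23 of 66 and 0 of 77 reads, and one TPM1 junction 0 of 22 and 54 of 160 reads. One MYL6 junction took 1 of 126 and 5 of 22 reads at its donor.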

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

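Signals were seen in reads that the comparisons above do not use. The globins HBG2, HBG1 and HBZ had mapped reads at their junctions in K562 although none was uniquely mapped, and the globins were looked up after the unique counts were seen. HBG2 had 12249 such reads in K562 and 3 in HepG2, HBG1 had 9776 and 1, and HBZ had 2704 and 1. HBE1 had 7580 mapped reads in K562, of which 230 were unique, while HBB had 26 and 23. Where the multi-mapped reads also map was not examined, so the split of these reads between globin genes is uncertain.

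Junctions assigned to more than 1 gene held 265419 unique reads in K562 and 320502 in HepG2. The most-read of them belongs to NME1 and the readthrough gene NME1-NME2 (chromosome 17, 51153663 to 51155650), with 14082 reads in K562 and 4062 in HepG2. The next, of HSPE1 and HSPE1-MOB4, had 7077 and 6873 reads.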

How the results depend on the processing

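No paired analysis was possible because each cell line has 1 pooled table, and for the same reason no sample could be left out. The 11 alternatives left the count of genes higher in K562 between 1303 and 2656 and in HepG2 between 1800 and 2629, all within 1.5 times 1836 and 2402. Of 125 list medians under an alternative, 118 stayed within the interval of the original median. Those intervals reflect the spread between list members and can be wide, as for stroma markers (-7.77 to 11.29). Staying within them is therefore a weak check of the processing. The cause of the changes below was not tested unless stated. With total-read scaling, which adds the same shift to every gene, the medians were 1.373 for large-subunit and 1.601 for small-subunit ribosomal proteins, 0.945 for translation factors, 0.553 for replication and mitosis and 0.535 for oxidative phosphorylation. The small-subunit median was 0.663 without each gene's most-read junction and 0.688 with junctions 60 or more coding bases after the start codon, chosen after seeing the data. The counted junctions of the usage comparison were 500 with 50 or more reads, 271 with a 40-point limit and 427 with donors only, which test fewer sites or set a stricter limit. With 5 or more reads, 81963 K562 junctions were detected.

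Differences in region share, K562 minus HepG2 in percentage points, moved for coding junctions to -4.0 with all mapped reads, -6.58 with untranslated annotation first, -3.6 without the 20 most-read genes of each table and -3.81 without ribosomal protein genes, the last chosen after seeing the data. In the same order, 5′ untranslated junctions gave 3.08, 4.0, 2.78 and 2.89. For 3′ untranslated junctions the first was 0.00856, a change of sign, the second -0.983 and the third -0.0454. Noncoding junctions gave 0.91, 3.57 and, without ribosomal protein genes, 0.928. Among named genes called higher in a line, 2 values changed sign, both to a log2 ratio of 0.13, KRT18 without its most-read junction and RPS7 with all mapped reads. Of the others under an alternative, 277 stayed in their interval and 194 moved beyond it, some of them to the other sign in genes without a call, such as TFRC to 0.20 with total-read scaling and RPL30 to 0.54 without its most-read junction.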

Other observations

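Over all measured genes, those of the splicing list included, coding exons between alternative junctions differed between the lines in both directions. By the junction that enters the exon, 119 exons passed the 20-point limit. Of these, only 41 had enough reads and also passed on the leaving side, 15 included more in K562 and 26 more in HepG2. The others can be alternative ends as well as cassette exons. Of the 41, 21 (51.2%, 35.1 to 67.1) had a length that is a multiple of 3, against 405 of 755 (53.6%) variable exons that did not pass on the entering side, a share within that interval. The 755 exons were not selected on the leaving side. Of the 119 exons, selected on the entering side alone, 61 (51.3%, 41.9 to 60.5) had such a length. An exon of ADD3 of 96 bases (chromosome 10, 110132305 to 110132400) was included in 87.0% (73.7 to 95.1) in K562 and 18.3% (11.9 to 26.4) in HepG2 on the entering side and in 89.7% and 25.2% on the leaving side. An exon of ADGRG6 of 84 bases was included in 100% and 32.1% on the entering side and in 100% and 55.4% on the leaving side. The count on both sides and these genes were chosen after values were seen.

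Neighboring genes also moved together. In windows of 20 genes, the median relative to all genes was 4.58-fold higher in K562 from SNAP29 to MMP11 on chromosome 22 (20858983 to 23784316), and 17 of the 20 genes lay above the all-gene median. It was 5.85-fold higher from HDGF to COPA on chromosome 1 (156742107 to 160343400). In HepG2 the largest value was 11.2-fold, from IFI27L1 to SETD3 on chromosome 14 (94081282 to 99480889), a window that holds the SERPINA genes of the liver, and it was 4.55-fold higher from DTD1 to ZNF337-AS1 on chromosome 20. Windows were ranked after the ratios were seen.

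Of the tests that follow, only that of distant coding junctions on chromosome 20 was set before its result was seen, and its value was re-expressed relative to all genes afterwards. The other tests, the 60-base limit, the choice of plasma genes and leaving out AFP were chosen after the results were seen. Chromosome medians of the gene ratios, relative to all genes, ran from -1.31 (-1.51 to -1.13) on log2 scale for 301 genes of chromosome 20 and -0.76 for chromosome 14 to 0.53 for the X chromosome. A median as low as that of chromosome 20 arose in 0 of 10000 shuffles of the ratios over genes, which argues against chance placement. With coding junctions 60 or more bases from the start codon, the chromosome 20 median was -1.35, which argues against the excess of reads near start codons in K562. Extra copies of chromosomes 2, 14, 16, 17 and 20, which HepG2 is known to carry, are a candidate explanation, since all 5 medians lay below 0 and their highest upper bound was -0.21. Chromosomes 3, 10 and 13 were also below 0 with their intervals, at -0.32, -0.20 and -0.34, and chromosome 22 was at -0.20 with an interval that holds 0. Copy number was not measured here in either line, and a ratio between the lines cannot tell a gain in HepG2 from a loss in K562.

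The larger share of 5′ untranslated junction reads in K562 was weighed next. A few abundant genes would leave the within-gene difference near 0, and its median was 0.77 over 1423 genes. Initiating ribosomes next to junctions would leave distant junctions alone, but those more than 30 bases before the start codon still differed by 0.71 (0.62 to 0.78) in 756 genes. Both argue against these as the whole cause. A difference between the library preparations of the lines may still be the source and cannot be told apart from a difference between the cells, because there is 1 table per cell line.

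Traces of hepatocyte transcripts in the K562 table could be reads carried over from HepG2 in one constant share. Over 15 plasma protein genes with more than 10000 HepG2 reads, K562 held 298 reads against 1415367 in HepG2. The dispersion of that ratio was 9.64, above all 10000 simulations with one ratio and counting error only. If reads are independent, that argues against one constant share with AFP included, which alone held 162 of the 298 reads. With AFP left out, the dispersion over 14 genes was 1.64, reached in 697 of 10000 simulations, so carried-over reads and low expression cannot be told apart at these counts for those 14 genes. AFP is not the only departure, since C3, from another list, had 112 reads in K562 and 97115 in HepG2.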
